A study of Rattus norvegicus with 4 samples.

How the data were processed

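RNA from the testis of male Sprague Dawley rats was hybridised to 4 Affymetrix rat U34 arrays of set A, 2 for a control sheep immunoglobulin and 2 for an antibody against rat FSH, each given for 4 days. The groups were taken from the source names in the labels. The title of antibody replicate 2 names postnatal day 4 in place of the treatment, so its group rests on the source name and the treatment protocol. The labels also disagree on age elsewhere. The series design gives day 14 as the start of injections. The treatment protocol gives day 18 as the start and day 22 as the collection, and the sample descriptions give day 18. Per the labels' protocols each RNA sample was a pool of about 20 organs, which that text calls ovaries although each source name says testis and names 1 animal; p-values then measure the spread between these RNA samples, and how many animals each stands for is not settled by the labels.

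The deposited values are linear intensities, 1 per probe set, with 1 decimal. The software and the scaling step are not given in the sources used here. Tested on the values, the mean without the lowest and highest 2% of probe sets was 125 on each of the 4 arrays, so each array had been scaled to a common level before deposit. Scale and direction are therefore known from the values, while the background correction is unknown. No detection calls were used, so whether a probe set was above background cannot be told from these values, and 6, 5, 3 and 2 probe sets were listed at 0 on the control and antibody arrays. The array medians of the log2 values differed by at most 0.103, and no further normalization was applied.

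Of the 8799 probe sets, 59 controls were left out of the tests. Gene symbols came from a platform annotation table and were updated through the Entrez identifier with a RefSeq gene table of assembly GRCr8. A single symbol was found for 7018 probe sets (6994 updated, 24 kept as annotated), several symbols for 308 and none for 1473, which are unnamed here. Transferrin, fixed in advance as a gene to report, is not named because its probe sets pair with several symbols. No genome positions are given because the sources used here name no genome build.

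Values were analysed as log2(intensity + 16). Probe sets with a mean log2 value at or above the 40th percentile were kept (5252). The groups were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For gene lists, 1 probe set per gene was used, the brightest over all 4 arrays (3169 genes), with camera at a preset correlation of 0.01, and 22 lists were fixed, of which 21 had at least 3 tested genes. The ribosomal list was a name pattern that also took in 1 tested ribosomal protein kinase gene. Named genes were, per direction, the 12 symbols with the smallest unadjusted p among single-symbol probe sets with no overlap between groups and a log2 change of at least 0.585, all called genes, the 3 members of each list with the smallest p and any member that passed over its list alone, and Fshr, Inha, Inhbb, Tf, Shbg, Star and Kitlg. The groups, lists, tests, naming rule and alternatives were fixed before the data were examined, except where stated.

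The alternatives were quantile normalization, centring on array medians, a constant of 1 or 64, no filter or a filter at the 60th percentile, no intensity trend, no moderation, a 1.5-fold threshold with an unadjusted p, leaving out each array, the replicate number as a block, an estimated correlation in camera, the rotation test fry and the mean of a gene's probe sets. With an estimated correlation, camera draws that correlation and its test from the residual degrees of freedom, which are few with 4 arrays. That test could hardly call any list here, so failing it does not count against a list. The same functions were tested on 20 simulated data sets of this comparison with 200 of 5252 probe sets changed. They recovered 71.2% of 2-fold and 98.2% of 4-fold changes, 5.58% of calls were false, and 5.00% of unchanged probe sets had an unadjusted p under 0.05. In the simulated gene lists (15 genes each, median of 3179 genes), a list shifted by 0.5 was called in 20 of 20 data sets, and 1 other list was called in all of them together. The noise was drawn independently for each gene, so these lists held no correlation between genes. They cannot show how camera fares where genes of a list vary together. The share recovered holds for 200 changes of these sizes and could differ with fewer. For probe sets too the noise was normal and independent, with variances drawn from the distribution that limma fitted to these arrays. The rates of false calls therefore check the code. They cannot show whether that distribution holds for the real arrays.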

Results

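Gene expression was measured in the testis of Sprague Dawley rats, an outbred laboratory strain, that had been injected for 4 days either with an antibody against follicle-stimulating hormone (FSH) or with a control immunoglobulin. By the treatment protocol, injections began on day 18 of age and collection was on day 22. The series design gives day 14 as the start instead. The title of antibody replicate 2 names postnatal day 4. The labels do not settle which age is right. FSH is the pituitary hormone that acts on the Sertoli cells, the cells that nurse the developing germ cells, and the antibody was given to suppress it. Each treatment had 2 RNA samples, each on 1 Affymetrix rat U34 array of set A, so there were 4 arrays. The table held an intensity for 8799 probe sets, and 5252 of them were bright enough to be tested. The median intensity was 39.2 and 36.5 on the control arrays and 38.8 and 40.4 on the antibody arrays. Intensities below are mean ± SD with n = 2 arrays per group, and log2 changes are the antibody group minus the control group ± SE, on the log2(intensity + 16) scale, which understates the change of dim genes. Where several probe sets of a gene are given, they are those bright enough to be tested. The number of arrays limits the precision of every value.

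The comparison asked which transcripts differ in the testis when FSH is suppressed for a few days. Named genes that rose were 3 in number. Testin, a protein secreted by Sertoli cells (probe set U16858_at), went from 30.7 ± 3.46 in the controls to 121 ± 9.55 after the antibody, a log2 change of 1.56 ± 0.18 (limma, adjusted p = 0.0152). Igfbp3, which binds insulin-like growth factors in the extracellular space, rose on both of its probe sets, from 17.5 ± 10.1 to 113 ± 9.19 (1.98 ± 0.24, adjusted p = 0.0152) and from 116 ± 35.2 to 363 ± 53.0 (1.54 ± 0.22, adjusted p = 0.0365). Foxq1, a forkhead transcription factor, rose from 36.7 ± 1.48 to 115 ± 7.50 (1.31 ± 0.18, adjusted p = 0.0302).

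Named genes that fell were 7 in number, each on at least 1 probe set. The transcript of Star, the protein that moves cholesterol into mitochondria for steroid synthesis, fell from 81.1 ± 7.28 to 19.2 ± 8.98, with a log2 change of −1.49 ± 0.23 (adjusted p = 0.0418). A second Star probe set gave −1.38 ± 0.25, with an adjusted p of 0.0653. Nptx2, a secreted pentraxin known from neurons, fell from 253 ± 19.0 to 67.8 ± 11.9 (−1.69 ± 0.18, adjusted p = 0.0152), and its second probe set gave −0.95 ± 0.17 (adjusted p = 0.0703). Both Nptx2 probe sets were designed from the same sequence, so their agreement is not independent. Alas2, the erythroid enzyme of the first step of heme synthesis, fell from 188 ± 42.1 to 62.4 ± 14.8 (−1.38 ± 0.21, adjusted p = 0.0418). Gucy1b1, a subunit of the soluble guanylate cyclase, fell from 192 ± 56.4 to 62.6 ± 1.98 (−1.37 ± 0.21, adjusted p = 0.0418), and Arl2, a small GTPase, from 123 ± 36.3 to 37.2 ± 6.08 (−1.37 ± 0.22, adjusted p = 0.0479). Probe sets disagreed for the remaining genes. Grhpr, a glyoxylate reductase, fell on 1 probe set (−1.21 ± 0.18, adjusted p = 0.0389) and gave −0.19 and −0.37 on its other probe sets, which were not called. Hspa9, a mitochondrial chaperone, fell on 1 probe set (−1.01 ± 0.16, adjusted p = 0.0479), while its other probe sets gave 0.08 and −0.02.

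**Figure D1:**
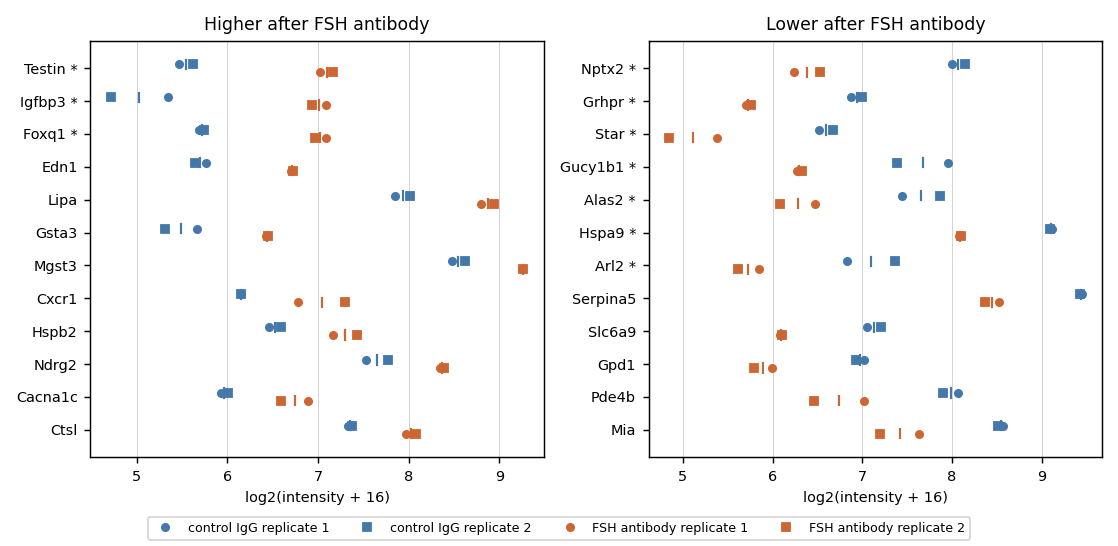
Log2(intensity + 16) on each of the 4 arrays for the 12 named genes with the smallest p in each direction (left, higher after the antibody; right, lower); circles and squares are the arrays of each group, vertical ticks the group means, and an asterisk marks an adjusted p under 0.05. In every gene shown the arrays of the 2 groups do not overlap, by the rule that chose them; Nptx2 goes from a mean intensity of 253 to 67.8 and Testin from 30.7 to 121.

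Further genes had separate groups and changes of at least 1.5-fold without passing the adjusted threshold. Separate groups say little alone: with 2 arrays against 2 they arise by chance in 33.3% of probe sets. Here 1966 of the tested probe sets (37.4%) had them. Higher values were found for Edn1, the vasoconstrictor peptide endothelin 1 (1.01 ± 0.18, adjusted p = 0.0653), and for the lysosomal lipase Lipa (0.94 ± 0.17, adjusted p = 0.0703). The glutathione transferases Gsta3 (0.94 ± 0.20, adjusted p = 0.142) and Mgst3 (0.71 ± 0.16, adjusted p = 0.184) were also higher. So were Cxcr1 (0.89), Cacna1c (0.77), Hspb2 (0.77), Ndrg2 (0.72) and the protease Ctsl (0.67), with adjusted p from 0.184 to 0.227. Lower values were found for the protease inhibitor Serpina5, with 677 ± 7.57 in the controls and 333 ± 25.7 after the antibody (−0.99 ± 0.16, adjusted p = 0.0541), the glycine transporter Slc6a9 (−1.04 ± 0.17, adjusted p = 0.0541), the glycerol phosphate dehydrogenase Gpd1 (−1.08 ± 0.18, adjusted p = 0.0541), the cAMP phosphodiesterase Pde4b (−1.25 ± 0.21, adjusted p = 0.0561) and Mia (−1.13 ± 0.19, adjusted p = 0.0561).

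By limma with Benjamini-Hochberg adjustment, 14 of the 5252 probe sets passed, 6 higher and 8 lower. They were 11 probe sets of the 10 genes above, 1 that pairs with several symbols and 2 without a symbol. At an unadjusted p under 0.05 there were 426, with 262.6 expected by chance, 209 of them higher and 217 lower; with each array centred on its median the split was 136 higher and 268 lower, and with no filter 445 higher and 257 lower. All 14 calls ended with quantile normalization (smallest adjusted p 0.0615), with no filter (0.224), without moderation of the variances (0.323), without control replicate 1 (0.230) and without control replicate 2 (0.429), while 154 probe sets passed without antibody replicate 1 and 93 without antibody replicate 2. With median centring 4 of the 14 passed.

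Genes known to respond to FSH and cAMP moved both ways. The list was fixed without an expected direction for each gene. Neither the mixed directions nor a list test for a shift in 1 direction can therefore tell whether its members responded. Of 15 tested members of this list, Igfbp3 was called over all probe sets, and adjusted over the list alone 1 rose (Igfbp3) and 3 fell (Pde4b, Inha and Shbg). Inha, the inhibin alpha subunit that Sertoli cells make, had an intensity of 1406 ± 258 in the controls and 743 ± 86.5 after the antibody, a log2 change of −0.90 ± 0.19 with an adjusted p of 0.122 over all probe sets; its second probe set gave −0.49 ± 0.24. Shbg, which encodes the androgen-binding protein, went from 874 ± 23.7 to 547 ± 23.6 (−0.66 ± 0.16, adjusted p = 0.217 over all probe sets). The FSH receptor transcript Fshr was at 71.0 ± 4.38 and 92.8 ± 30.0, a difference of 0.30 ± 0.22 that did not pass (adjusted p = 0.805). Inhbb, the inhibin beta B subunit, was too dim to be tested (21.8 ± 14.0 and 7.80 ± 3.96), as was the Sertoli cell ligand Kitlg. The list as a whole had a median log2 change of −0.04 and did not pass camera (adjusted p = 0.183). With no filter on dim probe sets it passed (adjusted p = 0.0347). An estimated correlation there gave an adjusted p of 0.854, but that test could hardly call any list with so few arrays.

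Among 17 tested Sertoli cell markers none was called over all probe sets. Adjusted over the list alone, Ctsl (0.56 ± 0.16 on its brightest probe set) and Amh, the anti-Müllerian hormone (0.52 ± 0.16), rose, and Inha, Shbg and A2m (−1.53 ± 0.34) fell. The other probe sets of A2m that passed the filter gave −0.41, −0.19 and −0.01. The list's median was 0.12 and its mean −0.03, and it did not pass (adjusted p = 0.964).

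Of 13 tested Leydig cell and steroidogenic genes, Star was called over all probe sets, and adjusted over the list alone Star and Fdx1 fell. Fdx1, which carries electrons to the mitochondrial steroid enzymes, had an intensity of 520 ± 88.9 in the controls and 265 ± 30.6 after the antibody (−0.93 ± 0.19, adjusted p = 0.116 over all probe sets). Cyp11a1, the enzyme that cleaves the cholesterol side chain, gave 0.52 ± 0.21 and did not pass. The list's adjusted p was 0.429, with a median of −0.09. Of 6 erythroid markers Alas2 was called, and the globin genes Hbb and Hbb-b1 gave −0.43 ± 0.25 and −0.24 ± 0.24 (list median −0.10, adjusted p = 0.259). The median of this list was −0.42 without control replicate 1 and 0.12 without control replicate 2. It was −0.09 without antibody replicate 1 and −0.38 without antibody replicate 2. Of 4 endothelial markers, all with higher values on their brightest probe sets, Edn1 rose when adjusted over the list alone. Flt1 gave 0.40 ± 0.19, and Nos3 gave 0.10 on its brightest probe set and 0.47 and −0.03 on the other tested ones. The list's median was 0.25 and its adjusted p 0.10.

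The 9 tested genes of meiotic spermatocytes had a median change of −0.28 and none passed; H2bc1, a testis histone, gave −0.57 ± 0.31, Adam2, a sperm surface protein, 0.46 ± 0.26 and Pdha2 −0.43 ± 0.27. Some germ cell genes differed widely between arrays of 1 treatment. Among genes picked out after their values were seen, Ldhc, the germ cell lactate dehydrogenase, was at 41.6 and 333.6 on the control arrays and at 143.6 and 41.3 on the antibody arrays, and Hspa2, a germ cell heat shock protein, at 150.1 and 505.9 and at 358.1 and 142.6. The meiotic list did not pass camera (adjusted p = 0.259). Its median was −0.60 without control replicate 1 and −0.52 without antibody replicate 1, and over all settings it ranged from −0.60 to −0.06. The 5 spermatid genes had a median of 0.08 (adjusted p = 0.964), with Tnp1, a transition protein, at 0.25 ± 0.26, Spa17 at −0.27 ± 0.38 and Odf2 at 0.14 ± 0.26, and the direction of each turned when 1 array was left out. Of 9 spermatogonia markers Ccnd2, a G1 cyclin, fell when adjusted over the list alone (−0.64 ± 0.18), and Epcam (0.45) and Ret (0.63) did not pass (list median −0.05, adjusted p = 0.876).

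**Figure D2:**
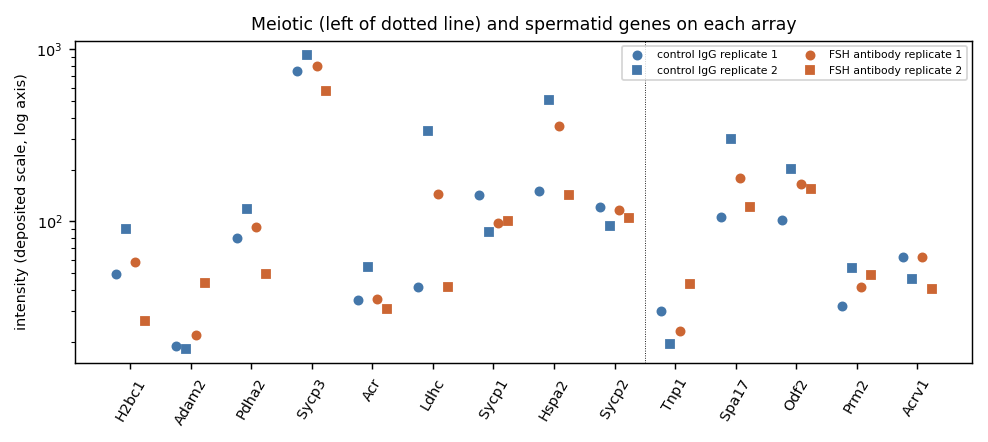
Intensity of tested meiotic spermatocyte and spermatid genes on each of the 4 arrays, on a log axis. Ldhc lies at 41.6 and 333.6 on the control arrays and at 143.6 and 41.3 on the antibody arrays, so the arrays of 1 group are farther apart than the group means.

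No member of the 11 immediate early genes passed when adjusted over the list alone. Jun gave 0.60 ± 0.18. Probe sets of Egr1 disagreed, with 0.43 ± 0.18 on the brightest and 0.38, 0.23 and −0.08 on the others, as did those of Nr4a1, with −0.87 ± 0.35 on the brightest and 0.12 on the other. By the brightest probe sets 9 of the 11 had higher values, with a median of 0.28 and an adjusted p of 0.10 by camera. Over all settings the median of this list ranged from 0.20 to 0.37. In the 27 genes of the TGF-beta family and growth factors Igfbp3 rose and Inha fell when adjusted over the list alone, while Smad3 gave −0.80 ± 0.23 (median 0.06, adjusted p = 0.608). Macrophage and immune markers (11 tested, median 0.36, adjusted p = 0.588) included C1qb at −0.71 ± 0.23 on its brightest probe set and 0.06 ± 0.26 on the other, Lyz2 at 0.60 ± 0.22 and RT1-Ba at 0.51 ± 0.20. Peritubular myoid and smooth muscle markers (9 tested, median −0.03, adjusted p = 0.664) included Cald1 at −0.37 ± 0.18, Myl9 at −0.30 and Cnn1 at 0.33. In 14 apoptosis genes (median 0.11, adjusted p = 0.429) Casp1 gave 0.40 and Bcl2l2 0.36, while Casp2 gave 0.27 on its brightest probe set and 0.23 and −0.39 on the others. In 20 cell cycle genes (median −0.07, adjusted p = 0.950) Mcm6 gave 0.26, Mcm5 −0.21 and Ccne1 0.23. In 9 cell junction genes (median −0.01, mean 0.04, adjusted p = 0.876) the gap junction protein Gja1 gave −0.71 ± 0.20, Jup 0.46 ± 0.17 and Cdh2 0.48 ± 0.18. None of these members passed, adjusted over its list alone, except Igfbp3 and Inha.

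The remaining lists had medians near 0 and no member that passed, with 1 exception. Extracellular matrix genes (21 tested, median 0.11, adjusted p = 0.964) included Timp2 at −0.44 and Col1a2 at 0.29, while Sparc gave −0.29 on its brightest probe set and −0.17, 0.20 and 0.33 on the others. Cholesterol synthesis genes (14 tested, median 0.07, mean −0.0064, adjusted p = 0.964) included Idi1 at −0.29. Acat2 gave −0.50 on its brightest probe set and 0.02 on the other, and Fdft1 gave 0.28 on its brightest and 0.04, −0.04 and −0.37 on the others. Heat shock and stress genes (16 tested, median 0.01, with the test's direction down, adjusted p = 0.964) included Cryab at 0.57, Hmox1 at −0.40 and Hsph1 at −0.33. Glycolysis and lactate genes (14 tested, median 0.02, with the test's direction down, adjusted p = 0.964) included Slc2a3 at 0.21, Pfkm at 0.14 and Slc16a1 at −0.17, whose second probe set gave −0.78. Adipose markers (4 tested, median 0.04, mean −0.03, adjusted p = 0.964) included Cfd at −0.68, Lpl at 0.46 and Lipe at 0.13. Cytosolic ribosomal protein genes (41 tested, median 0.05, adjusted p = 0.808) included Rpl3l at 0.53, Rpl19l4 at 0.72 and Rps3 at 0.34. The median of this list was 0.16 without control replicate 2 and −0.07 without control replicate 1. The exception was Adam7, 1 of only 2 tested epididymis markers, with 18.6 ± 0.636 in the controls and 36.1 ± 3.25 after the antibody (0.59 ± 0.21). It passed over this list of 2 genes alone, but over all probe sets its adjusted p by limma was 0.534. Its mean log2 value of 5.41 lay near the filter level of 5.30. Cst8 gave −0.17, and this list was too small for camera.

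**Figure D3:**
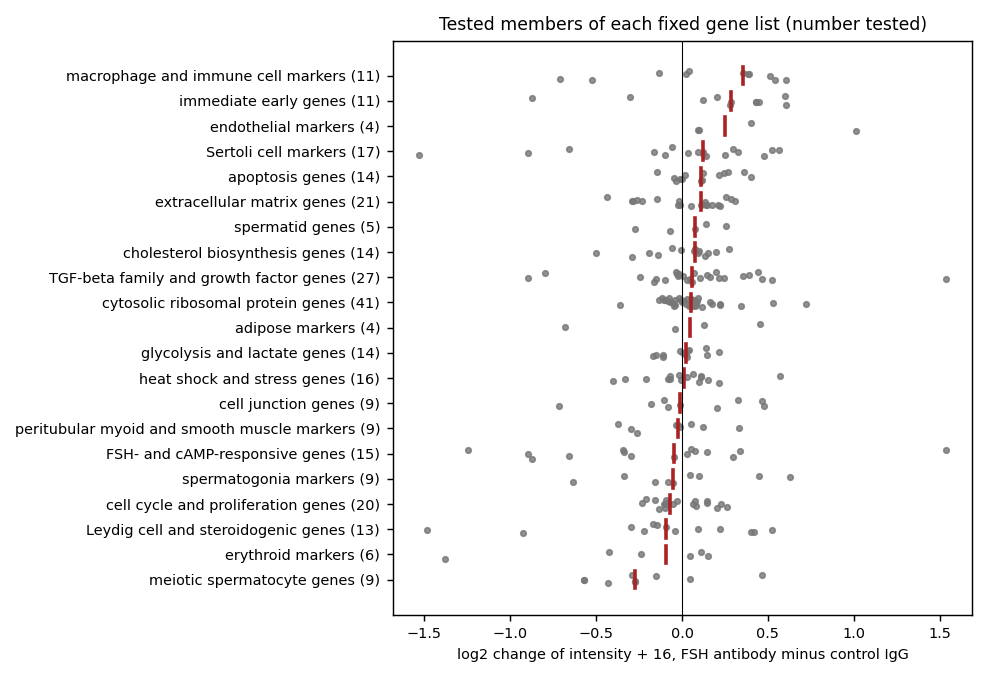
Log2 change (antibody minus control) of each tested member of the gene lists, 1 point per gene, with a red tick at the list's median. All lists except the endothelial markers have members on both sides of 0, and 0 of the 21 tested lists passed camera.

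Of the 21 lists, 0 passed camera with its preset correlation, and with an estimated correlation the smallest adjusted p was 0.875. The test with an estimated correlation could hardly call any list with so few arrays. The ratio of 3′ to 5′ signal of the control transcripts, a measure of RNA integrity, was compared per array. For beta-actin the log2 difference was 1.01 ± 0.20 in the controls and 1.15 ± 0.07 after the antibody, and for GAPDH −0.05 ± 0.15 and −0.07 ± 0.01. Two-sided exact permutation tests gave p = 0.667 for beta-actin and p = 1 for GAPDH, where 2 arrays against 2 allow no p below 0.333. Spiked bacterial controls were compared without a test. BioB-M was at 147.4 and 198.4 on the control arrays and at 110.4 and 120.3 on the antibody arrays. The log2 difference between groups was −0.51 for BioB-M, −0.48 for BioB-5 and −0.49 for CreX-5, but 0.09 for BioC-3 and 0.12 for BioC-5.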

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

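The ribosomal list without its kinase gene, and an estimated correlation with 1 array left out or no filter, were chosen after seeing the data; the other alternatives were planned. None of the 14 called probe sets turned in direction, which says little, since their groups do not overlap and most settings cannot turn them; 10 of them were tested at the 60th percentile filter. In every setting 82 of 87 named probe sets and 7 of 21 list medians kept their direction. The cause of the changes below was not tested, except that the filters change the number of probe sets tested and leaving out an array leaves 1 residual degree of freedom, with the lone array assumed to vary like the other group. Without detection calls, signal over background cannot be given, so how far dim probe sets weigh on the counts is not known. The 60th percentile filter called 13 probe sets, 10 of them shared with the main calls, while no filter called 0.

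Against 14 called probe sets (6 higher, 8 lower), 0 were called with quantile normalization (0 higher, 0 lower), 0 with no filter and 0 with no moderation, where 420, 702 and 352 had an unadjusted p under 0.05 by limma or by its fit without moderation. Median centring called 4 (3 higher, 1 lower), a constant of 1 called 10 (6 higher, 4 lower), no intensity trend 10 (6 higher, 4 lower), and 180 passed an unadjusted p under 0.05 with 1.5-fold. Leaving out 1 array gave 0 to 154 calls, 0 to 34 higher and 0 to 120 lower. At an unadjusted p under 0.05, against 209 higher and 217 lower, median centring gave 136 higher, no filter 445 higher and 257 lower, the 60th percentile filter 135 higher and 142 lower, and leaving out 1 array 102 to 316 higher and 161 to 390 lower.

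The labels name different animals for same-numbered arrays, but they also describe each RNA sample as a pool, so they do not settle pairing. The correlation across probe sets of their deviations was 0.00386, which gives no sign of pairing. It cannot exclude pairing, since shared effects in opposite directions can cancel. At an unadjusted p under 0.05 by limma, replicate 1 against replicate 2 gave 249 probe sets and the remaining split that ignores treatment gave 140, with 262.6 expected by chance. With the replicate block 39 probe sets were called, 12 higher and 27 lower, 14 of them shared with the main calls. This fit also leaves 1 residual degree of freedom, so the larger count need not mean a gain from pairing.

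Against 0 lists called, no filter called 1 (the FSH and cAMP list, median −0.15, adjusted p = 0.0347). Leaving out 1 array also made some lists pass, in fits with 1 residual degree of freedom. An estimated correlation in the same fits called 0 lists, but with so few arrays it could hardly call any, so this decides nothing. The direction of 5 named genes turned only when 1 array was left out, with log2 changes of −0.045 to 0.55 for Tnp1, −0.97 to 0.42 for Spa17, −0.30 to 0.58 for Odf2, −0.60 to 0.13 for Hbb-b1 and −0.34 to 0.0018 for Cst8. List medians that turned when 1 array was left out ranged over −0.095 to 0.021 for Leydig cell genes, −0.13 to 0.043 for myoid markers, −0.15 to 0.032 for spermatogonia, −0.19 to 0.34 for spermatids, −0.42 to 0.12 for erythroid markers, −0.018 to 0.16 for adipose markers, −0.027 to 0.024 for cell cycle genes, −0.039 to 0.18 for cell junction genes, −0.11 to 0.19 for extracellular matrix, −0.074 to 0.10 for cholesterol synthesis, −0.042 to 0.10 for heat shock genes, −0.031 to 0.020 for glycolysis and −0.071 to 0.16 for ribosomal protein genes. Other settings that turned a median were median centring (adipose −0.0023, heat shock −0.034, glycolysis −0.026), quantile normalization (cell junction 0.0050), the 60th percentile filter (cell junction 0.20, heat shock −0.013, TGF-beta −0.017) and the mean of a gene's probe sets (Leydig cell 0.056, spermatogonia 0.054, cell junction 0.20, heat shock −0.071).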

Other observations

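All patterns and tests of this part were chosen after the results were seen. Of 903 genes with several tested probe sets, 16 had an unadjusted p under 0.05 on all of them in 1 direction, 8 higher and 8 lower. Cdkn1a, an inhibitor of the cell cycle, gave log2 changes of −0.97 ± 0.22 and −1.04 ± 0.21, and Slc11a2, an iron transporter, gave −0.64 ± 0.20, −0.52 ± 0.17 and −0.72 ± 0.19. Higher values were found on 3 probe sets of the kinase Map3k1 (0.47, 0.64 and 0.65) and on both of Id3 (0.43 and 0.93), Sdc4 (0.36 and 0.39) and Slc37a4 (0.50 and 0.58). Except for 1 probe set of Star, 1 of Nptx2 and both of Igfbp3, none of these probe sets passed the adjusted threshold. For Sdc4, Slc37a4, Nptx2, Cdh2 and Ppdpf, all among the 16, both probe sets of the gene were designed from the same sequence. Their agreement is not independent. Some probe sets of Map3k1, of Slc11a2 and of Lipa also share a sequence. No number expected by chance was worked out for the 16 genes.

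Among probe sets without a symbol, all 7 tested ones designed from the sequence M13100 had higher values after the antibody (median 0.82, 6 with an unadjusted p under 0.05), as had all 3 from X05472 (0.98 to 2.84). The other 2 sequences with 3 such probe sets did not show this: 0 of 3 were higher for J01435 and 2 of 3 for U36444. For either sequence 0 had an unadjusted p under 0.05. Agreement between probe sets designed from the same sequence is not independent. By limma, 1 of the X05472 probe sets was called (2.84 ± 0.39, adjusted p = 0.0302), and 0 of those from M13100. The called one was at 50.5 and 83.5 on the control arrays. On the antibody arrays it was at 930.9 and 342.9. Where the best probe set of a gene had an unadjusted p under 0.05, 143 of its 206 further probe sets (69.4%) went the same way, against 577 of 974 (59.2%) for other genes.

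The fall of Star and Fdx1 could come from fewer Leydig cells or from a faulty probe set. The other 11 tested genes of the Leydig cell list had a median log2 change of −0.040 (SD 0.29), against −0.93 for Fdx1. They ranged from −0.30 to 0.52, so the list as a whole did not fall by that size. A narrower set of 4 of these 11 genes, tried first, gave 0.03. Star and Fdx1 were picked for the largest falls in the list, so comparing the rest with Fdx1 cannot test the number of Leydig cells. The second probe sets of both genes were lower by at least 2.93 SE, which argues against a single faulty probe set. A response of these genes to the antibody treatment stays open as a hypothesis, as do a change in Leydig cell number and any difference between the pools other than treatment.

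The lower Alas2 value could come from less blood in the antibody samples. The bright globin genes Hbb and Hbb-b1 also had lower values (−0.43 ± 0.25 and −0.24 ± 0.24). A first test, the median of the other 5 tested erythroid genes, gave 0.05 but rests on dim genes such as Hba-a3 and decides nothing. The log2 difference of Alas2 from the mean of the bright globins changed by −1.05 ± 0.37, which with 2 arrays per group does not exclude blood as the cause. A fault of its only probe set (1 tested) also stays open.

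Genes of meiosis and spermatids, singled out after their values were seen, differed between arrays of the same treatment. Their median difference was 0.48 for control replicate 2 minus 1 (9 of 14 genes higher) and 0.30 for antibody replicate 1 minus 2 (10 of 14), orders chosen to give positive medians. Others went the opposite way, such as Sycp1 (−0.63) and Tnp1 (−0.38) in the controls and Adam2 (−0.66) with the antibody. No explanation was tested.

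Of the 3 splits of the 4 arrays into 2 and 2, 1 had as many probe sets at an unadjusted p under 0.05 as the split by treatment, namely the treatment split itself with 426, and the highest of the others had 249. With so few splits no share under 0.05 can be reached.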
